A study of Mus musculus with 8 samples.

How the data were processed

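The deposited files hold tag counts for 8 sequencing libraries, 1 file per library, with 1 line per position and strand and the number of aligned tags there. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Bowtie 1.1.1 and HOMER 4.7.2, and the build was mm9. Per the labels' protocols, libraries were amplified by PCR and sequenced as single reads of 50 nt. Alignment settings and treatment of duplicates are not given in the sources used here. The counts as deposited are not normalized, and every interval is 50 bp wide. Files of 3 libraries (the EGS plus formaldehyde input, H3K27ac replicate 1 and input replicate 1) include unplaced contigs, at 2.04%, 0.939% and 2.66% of positions, and the others do not. Comparisons used chromosomes 1 to 19 and X.

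Each position and strand was counted once, and tags were moved by 50% of the strand cross-correlation lag, which was 155 to 185 bp. For windows, tags were counted in 2639002 windows of 1 kb. Windows with fewer than 30 tags over the 6 formaldehyde libraries, and 6845 windows with input over 10 times its median, were left out, which left 1279736. Library sizes were scaled by TMM factors of 10 kb bins. The edgeR (4.0.16, R 4.3.3) quasi-likelihood test was fitted to the 6 formaldehyde libraries with the group as the only term and 3 residual degrees of freedom, the dispersion trend taken from 100000 windows, and Benjamini-Hochberg FDR under 0.05. The first fit to the real counts used the estimator of version 4 of the package and called 0 windows for either antibody. The estimator that this version uses by default was then taken for the results, after that count had been seen.

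Both estimators were tested on simulated data, after the fits to the real counts had been seen. Counts were drawn for the 1279736 windows with H3K27ac raised in 20000 windows at a dispersion of 0.2. The default estimator called 14.1% of windows raised 4-fold, 64.8% raised 8-fold, 96.6% raised 16-fold and 99.9% raised 32-fold, and 2.80% of its calls were false. The version 4 estimator called 5.06%, 37.6%, 85.3% and 98.8%, with 0.744% false. With only 200 windows raised, the default called 0%, 14.0%, 68.0% and 96.0% and the version 4 estimator called none. At a dispersion of 0.1 with 200 windows raised, the version 4 estimator called 0%, 14.0%, 66.0% and 98.0%, with 0 false calls. The default then called 2.00%, 66.0%, 100% and 100%, with 4.29% of its calls false. An earlier version of this simulation applied the scaling factors to library sizes once too often and was corrected. All windows of a simulation had the same dispersion. In the real counts the median fitted dispersion was 0.211 with the default estimator and 0.314 with the version 4 estimator. With the default in windows of at least 100 tags it was 0.414. The simulated shares of false calls therefore need not hold for the real calls.

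Peaks were called in single libraries with a Poisson test in windows of 200 bp moved by 50 bp, against the largest of the genome mean and the library's own input in 1 kb and 10 kb scaled by total tags, at FDR under 0.001 and at least 4-fold. Peaks overlapped when they shared 1 bp. Chance overlap came from 100 circular shifts of the peaks along their chromosomes. No shift reached the observed value for any comparison (permutation p = 0.0099, the smallest the shifts can give). Shifted peaks can fall anywhere on a chromosome, so the shifts do not account for signal that all libraries share. In simulated libraries with peaks planted on chromosome 19, a library as deep as Bcl11b replicate 1 recovered 4.0% of peaks planted at 10-fold, 34.0% at 20-fold and 90.0% at 40-fold. A library as deep as replicate 2 recovered 90.0% at 10-fold and 100.0% at 20-fold, with 0 calls off target in each. Background and control were drawn from the same smoothed input, so this 0 says little about false peaks in real libraries. Real inputs called against each other gave 424 to 80932 peaks. No test between groups was made from peaks. Shares of tags have 95% Wilson intervals, which cover counting error only.

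The labels name an input of the same number for each antibody, and samples of a number share an age, so the number was read as a shared experiment and added as a block in an alternative fit. Deviations from the group means correlated across windows at 0.34 between Bcl11b and H3K27ac, -0.03 between Bcl11b and input and -0.14 between H3K27ac and input.

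Except for those listed after it, regions named in the text follow a rule set before the data were examined: the 10 peaks with the highest fold over input, by the lower replicate, and the 5 longest regions of called H3K27ac windows merged over gaps of up to 2 kb. Outside that rule are the Bcl11b window on chromosome 11, which is the one with the smallest p, and the chromosome 13 bin and X windows of the last part, which were picked from the data. The reference table used here is of another build (GRCm38.p6), so regions are given by mm9 position without gene names, and comparisons at promoters, gene lists and sequence motifs were not run. Alternatives set before the data were examined covered normalization, DESeq2 (1.42.0), filters, duplicates, window size, depth, the block, left-out libraries, peak thresholds, inputs and overlap. The other alternatives named in the closing section were added later. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.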

Results

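Chromatin immunoprecipitation sequencing was carried out on whole thymocytes of wild-type C57BL/6 mice, all labelled male. The antibodies were against Bcl11b, a zinc-finger transcription factor needed for T-lineage commitment, and against H3K27ac, a histone mark of active promoters and enhancers. The 8 libraries fall into 5 groups. Cells fixed with formaldehyde gave 2 Bcl11b, 2 H3K27ac and 2 input libraries, where replicate 1 came from mice of 11 weeks and replicate 2 from mice of 8.1 weeks. Cells fixed with EGS, a longer cross-linker that joins proteins to each other, followed by formaldehyde gave 1 Bcl11b and 1 input library, from mice of 11 weeks. The series as a whole concerns chromatin in early T-cell development, and these libraries ask where Bcl11b and H3K27ac lie in the thymocyte genome.

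The libraries held 18917702 to 47664833 tags. Counted once per position and strand, the Bcl11b libraries held 3640112 positions in formaldehyde replicate 1, 24713371 in replicate 2 and 15289725 with EGS plus formaldehyde. The H3K27ac libraries held 20935144 and 20194520, and the inputs held 10577438 in replicate 1, 36106097 in replicate 2 and 26978110 with EGS plus formaldehyde. Bcl11b replicate 1 had 5.20 tags per position, and the other libraries had 1.29 to 1.88, so its number of distinct positions was the smallest of the series. Levels below are given as normalised tags, scaled to a library of 1000000 positions.

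H3K27ac lay above input in 22963 windows of 1 kb and below it in 264, out of 1279736 windows tested (edgeR quasi-likelihood test, FDR under 0.05, 2 libraries of each kind). The windows merged into 10751 regions with a median width of 1 kb, of which 55.5% were a single window. The longest region, on chromosome 14 from 54773001 to 54859000 of build mm9, spanned 86 kb and had a median log2 fold of 5.01 over its called windows. H3K27ac there was 10.1 normalised tags per kb in replicate 1 and 7.42 in replicate 2, and the inputs were at 0.464 and 0.652. The next longest were a region of 43 kb on chromosome 12 from 108357001 to 108400000, one of 41 kb on chromosome 15 from 74726001 to 74767000, one of 38 kb on chromosome 18 from 61018001 to 61056000, and one of 37 kb on chromosome 15 from 66627001 to 66664000. Their median log2 folds were 4.91 to 5.30. With the replicate number as a block the count was 9894 windows above and 40 below input, all of them also called without the block. With libraries scaled by total tags the split was 6304 above and 4494 below. Leaving out any one of H3K27ac replicate 1, H3K27ac replicate 2, input replicate 1 or input replicate 2 left 0 calls, and the version 4 estimator of the same test, which was run first, also gave 0; the earlier estimator was made the main one after that was seen.

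For Bcl11b the same test called 0 windows above or below input, with 36871 windows (2.88%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.9998. DESeq2 called 437 windows above input and 0 below, but it gave no adjusted p for 1215749 of the 1279736 windows. The libraries differed in scale at their strongest sites. At the window on chromosome 11 from 103032001 to 103033000, Bcl11b was 77.9 in replicate 1 and 15.5 in replicate 2, over inputs of 3.30 and 0.992, in tags for each 1000000 positions of library size as adjusted by the TMM factors of the test, a scale not used for the other levels given here. This was a log2 fold of 4.46 with an SE of 1.02 and an adjusted p of 0.9998. The replicated test therefore gives no list of Bcl11b windows, and Bcl11b sites are described here from peaks called in single libraries. When the input of the EGS plus formaldehyde cells took the place of input replicate 1, a choice made after seeing the data, 7368 windows lay above input and 811 below.

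How far Bcl11b peaks of the formaldehyde libraries agreed depended on the settings. Formaldehyde replicate 1 had 14573 peaks, replicate 2 had 274090 and the EGS plus formaldehyde library had 48323. Of the peaks of replicate 1, 12331 (84.6%) overlapped a peak of replicate 2, against 8.18% on average when peaks were moved along the chromosomes. In the other direction, 11864 (4.33%) of the peaks of replicate 2 overlapped a peak of replicate 1. With both thinned to equal numbers of positions, 50.6% of the peaks of replicate 1 overlapped replicate 2, and 46.1% of those of replicate 2 overlapped replicate 1. With input replicate 1 used for both libraries, 4023 (27.6%) of the peaks of replicate 1 were shared, and with all tags 30160 (22.4%) of 134742 were. The 12331 sites covered 0.232% of the genome and held 24.2% (95% Wilson interval 24.2 to 24.3) of the tags of Bcl11b replicate 1, 6.46% (6.45 to 6.47) of replicate 2 and 7.54% (7.53 to 7.56) of the EGS plus formaldehyde library. H3K27ac had 9.16% (9.15 to 9.18) in replicate 1 and 14.6% (14.5 to 14.6) in replicate 2. The inputs had 4.15% (4.14 to 4.17) in replicate 1, 0.956% (0.953 to 0.960) in replicate 2 and 0.758% (0.755 to 0.762) with EGS plus formaldehyde. Input replicate 1 was thus itself enriched at these sites. Within 500 bp of the summits its mean was 11.8 times the genome mean. Input replicate 2 was at 3.23 times and the EGS plus formaldehyde input at 2.69 times. Intervals cover counting error only.

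**Figure D1:**
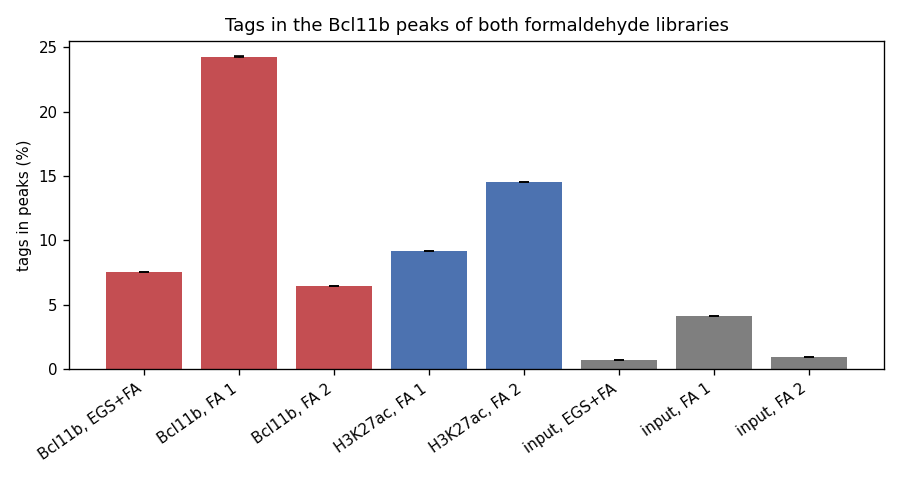
Percent of each library's tags (vertical axis) that fall in the 12331 Bcl11b peaks shared by the formaldehyde libraries, with 95% Wilson intervals too narrow to see; FA is formaldehyde. Bcl11b FA 1 is the highest at 24.2%, and input FA 1, at 4.15%, lies above the other inputs.

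The Bcl11b peak with the highest fold over input, ranked by the lower of the replicates, lay on chromosome 4 from 62254651 to 62255300. Its fold was 46.4 in replicate 1 and 58.7 in replicate 2. Within 500 bp of its summit, Bcl11b was at 87.3 normalised tags in replicate 1, 23.5 in replicate 2 and 34.0 with EGS plus formaldehyde, and the inputs were at 6.71, 1.25 and 1.71. The next were on chromosome 8 from 73219151 to 73219650, with folds of 56.2 and 46.0, and on chromosome 10 from 127935701 to 127936200, with folds of 45.8 and 45.1. The remaining peaks of the 10 highest began at 89147601, 121918501 and 26213301 on chromosome 8, at 32643701 on chromosome 16, at 34725351 on chromosome 4, at 102878101 on chromosome 11 and at 81537251 on chromosome 12. Their lower folds were 39.1 to 45.03. All 10 were peaks in the EGS plus formaldehyde library, and 6 were H3K27ac peaks in both replicates. At these 6, H3K27ac was 9.94 to 22.2 normalised tags in replicate 1 and 13.7 to 31.2 in replicate 2. The others were not without H3K27ac, at 6.22 to 13.9 and 8.86 to 17.1.

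Peaks of Bcl11b overlapped peaks of H3K27ac more often than moved peaks did, by a share that depended on the libraries used. H3K27ac had 55133 peaks in replicate 1 and 148286 in replicate 2, and 38458 (69.8%) of the first overlapped the second, against 6.04% when moved. Of the 12331 Bcl11b sites, 6648 (53.9%) overlapped an H3K27ac peak of both replicates, against 2.00% when moved. This share was 20.8% at a minimum of 8-fold and 33.7% with all tags. In libraries that share no input, 77.0% of the Bcl11b peaks of replicate 1 overlapped H3K27ac of replicate 2, against 5.28% when moved. In the other direction the overlap was 8.65% of the Bcl11b peaks of replicate 2 with H3K27ac of replicate 1, against 2.17%. Moved peaks can fall anywhere on a chromosome, so these contrasts cannot separate sharing between the antibodies from signal common to all libraries. Peaks of input replicate 1, set against input replicate 2, overlapped 84.7% of the 12331 sites. The share of H3K27ac tags in these sites was 2.21 times that of its own input in replicate 1 and 15.2 times in replicate 2. The share of Bcl11b sites with H3K27ac rested on the libraries used. It was 8.46% without Bcl11b replicate 1, 46.7% without Bcl11b replicate 2, 88.5% without H3K27ac replicate 1 and 54.0% without H3K27ac replicate 2.

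Sites with H3K27ac in both replicates had more Bcl11b than the others. Their median in the EGS plus formaldehyde library was 8.78 normalised tags against 3.93, in replicate 1 it was 20.1 against 10.7, and in replicate 2 it was 7.25 against 4.05. The inputs were higher there as well, at 4.86 against 3.89 in replicate 1, 1.36 against 0.942 in replicate 2 and 1.099 against 0.834 with EGS plus formaldehyde, so part of the difference is shared with input. The sites without H3K27ac peaks in both replicates had H3K27ac medians 7.64 and 13.2 times the genome mean in replicates 1 and 2. Input medians there were 10.3 times the genome mean in replicate 1 and 2.49 times in replicate 2. The H3K27ac median thus lay above that of its own input in replicate 2 but not in replicate 1. Peaks of H3K27ac replicate 1 were called against input replicate 1, itself enriched at these sites. Around the summits of Bcl11b replicate 1, which fix the centre for that library, H3K27ac was broader than Bcl11b. Density from 200 to 500 bp away at acetylated sites was divided by that within 100 bp on either side of the summit. For Bcl11b the ratio was 0.184 in replicate 1, 0.319 in replicate 2 and 0.350 with EGS plus formaldehyde. For H3K27ac it was 0.855 and 0.784, and for the inputs it was 0.455 in replicate 1, 0.664 in replicate 2 and 0.742 with EGS plus formaldehyde.

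**Figure D2:**
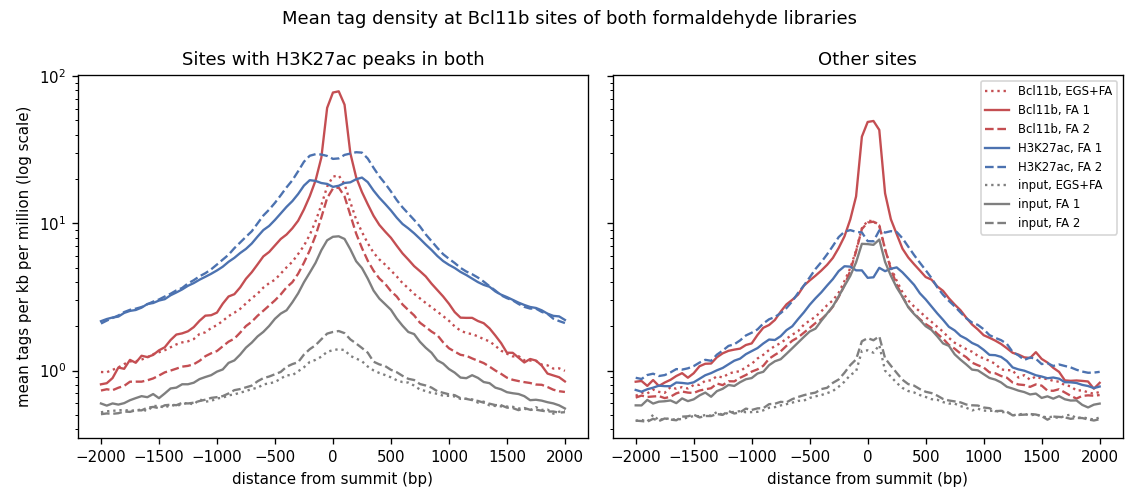
Mean normalised tags per kb (log axis) against distance from the Bcl11b summit in bp, at 6648 sites with H3K27ac in both replicates (left) and 5683 others (right). Solid lines are formaldehyde replicate 1, dashed lines replicate 2 and dotted lines EGS plus formaldehyde; Bcl11b falls faster from the summit than H3K27ac, and input FA 1 peaks there as well.

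The comparison of fixations rests on 1 Bcl11b library with EGS plus formaldehyde and has no replicate check. Of the 12331 sites found in both formaldehyde libraries, 10799 (87.6%) were also peaks with EGS plus formaldehyde, against 1.89% when moved. Without formaldehyde replicate 1 this share was 11.2%, of the 274090 peaks of replicate 2. Of the 48323 EGS plus formaldehyde peaks, 20.8% were in both formaldehyde libraries and 38.7% in neither. Another 39.4% were in replicate 2 only and 1.14% in replicate 1 only. This split moved with the settings. In the main setting 21.9% overlapped replicate 1 and 60.2% replicate 2. Thinned to equal numbers of positions the shares were 47.0% and 50.9%, and with all tags 13.4% and 39.1%. With input replicate 1 in place of input replicate 2, the share in replicate 2 was 35.6%. The peaks in both formaldehyde libraries had a median fold of 15.6 with EGS plus formaldehyde and overlapped H3K27ac of both replicates in 63.1%, and those in neither had a median fold of 7.78 and overlapped it in 33.0%. Across the 12331 sites, which are not independent replicates, the rank correlation of Bcl11b levels was 0.933 between EGS plus formaldehyde and replicate 2, 0.766 between EGS plus formaldehyde and replicate 1, and 0.838 between the formaldehyde replicates. Bcl11b replicate 1 had correlations of 0.754 with input replicate 1, itself enriched at these sites, 0.612 with input replicate 2 and 0.483 with the EGS plus formaldehyde input. The EGS plus formaldehyde Bcl11b library had 0.552 to 0.631 with the inputs.

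With equal numbers of distinct positions the numbers of peaks drew together, although tags per position still differed. With every library thinned to the size of the smallest, about 3631399 positions, the EGS plus formaldehyde library had 18622 peaks, formaldehyde replicate 1 had 14811 and replicate 2 had 17218. The H3K27ac libraries then had 27524 and 41403.

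**Figure D3:**
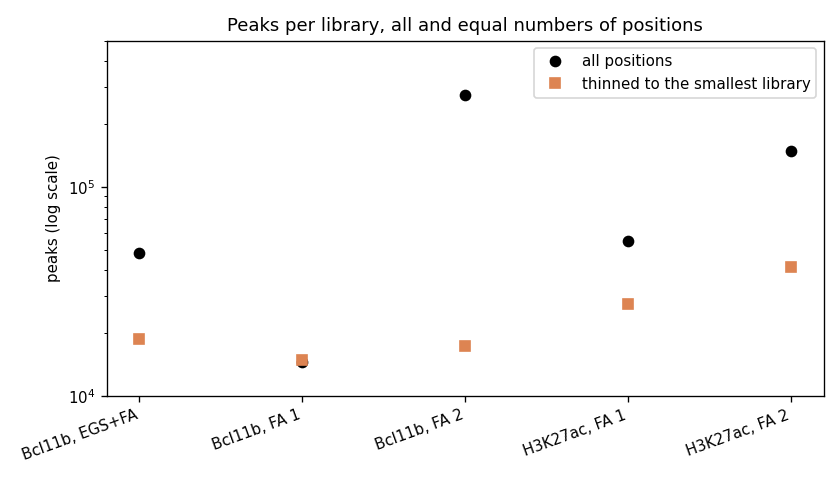
Peaks per library (log axis) from all positions (circles) and after thinning every library to the smallest (squares); FA is formaldehyde. The Bcl11b libraries range from 14573 to 274090 peaks from all positions and from 14811 to 18622 with equal numbers of positions.

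Replicate 2 differed from the 11-week libraries on Y and, in input and Bcl11b, in density on X. Its 3 libraries had 76.8 to 241 Y positions for each 1000000 autosomal positions, and the 11-week libraries had 417 to 2334. Density on X relative to the autosomes was 1.03 in input replicate 2, 0.699 in input replicate 1 and 0.582 in the EGS plus formaldehyde input. For Bcl11b it was 0.796 in replicate 2, 0.630 in replicate 1 and 0.480 with EGS plus formaldehyde, and for H3K27ac it was 0.380 in replicate 2 and 0.374 in replicate 1. At H3K27ac peaks of both replicates, however, the median log2 ratio of replicate 2 over replicate 1 was higher on X, at 0.479. The median of the autosomes was 0.268 and the highest autosome was at 0.345. All samples are labelled male.

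**Figure D4:**
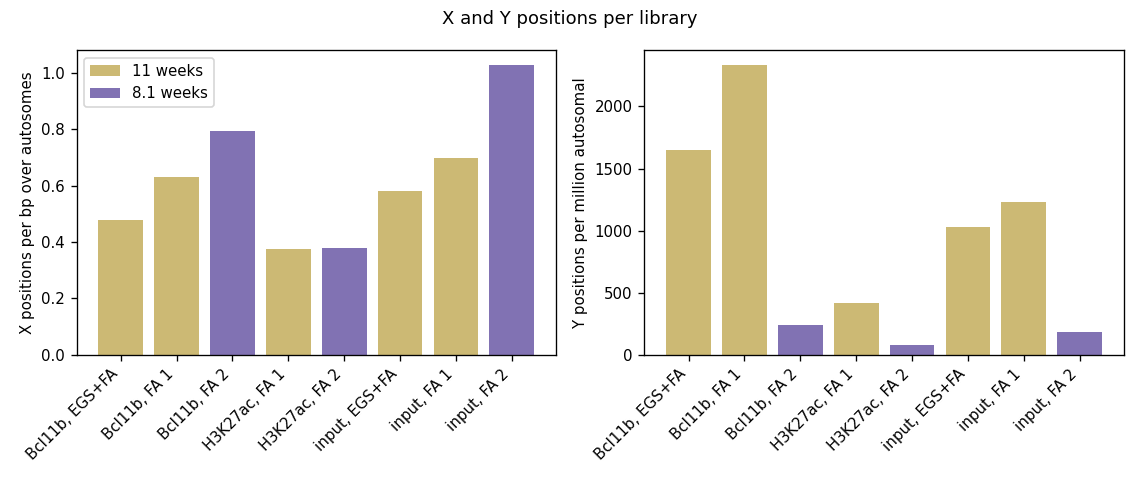
Density of X positions per bp over that of autosomes (left) and Y positions for each 1000000 autosomal positions (right) in each library, coloured by age; FA is formaldehyde. Input FA 2 has the highest X density, 1.03, and the replicate 2 libraries have the fewest Y positions, 76.8 to 241.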

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

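The tests of exact positions and of precipitated DNA in input replicate 1 were set before their results were seen, and the mixing share, X and Y, number of positions and input tests were chosen after.

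The formaldehyde input of replicate 1, which should show no antibody signal, had 80932 peaks when set against input replicate 2, and the reverse gave 6069. Its peaks covered 84.7% of the Bcl11b sites. Finished molecules of the Bcl11b replicate 1 library did not account for this, since exact sharing of positions at those sites was only 0.825 percentage points above the value after moving by a few bp. H3K27ac DNA met the criterion set before. Its libraries had 5.42% and 8.78% of their tags in peaks of this input, where independent tags of the input itself had 5.16%. By the mixing share, chosen after, it would put at least 18.4% of the tags into EGS plus formaldehyde peaks. This is over 2 times the 7.26% found. The mixing share takes the mixed DNA to have the profile of the sequenced library, and its limit was also chosen after. H3K27ac DNA is therefore not excluded. Bcl11b DNA did not meet the criterion set before, which asked for at least 5.16% in every Bcl11b library. Bcl11b replicate 1 had 13.3% of its tags in these peaks, and the other Bcl11b libraries fell below 5.16%. The criterion against it, with all of them below, was not met either. A mixture with Bcl11b replicate 1 would put 11.0% into EGS plus formaldehyde peaks. This is also above the 7.26% found but within 2 times of it, the limit chosen. Whether Bcl11b DNA was mixed in stays open, as does uneven shearing of open chromatin, which was not tested.

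Tags on the Y chromosome, which no comparison used, reached 2334 positions for each 1000000 autosomal positions in Bcl11b replicate 1, where the 3 libraries of replicate 2 had 76.8 to 241. Contigs that differ between alignments did not account for the Y gap, since among 11-week libraries without unplaced contigs the lowest was still 6.83 times the highest of replicate 2. Animals with 2 X chromosomes in replicate 2 were tested by X density outside peaks, where input replicate 2 was at 1.41 times input replicate 1 and 1.79 times the EGS plus formaldehyde input, and Bcl11b replicate 2 was at 1.29 and 1.81 times the 11-week Bcl11b libraries. The lowest lay between the limits of 1.2 and 1.5, chosen after the data were seen, so this test leaves the question open. Over all positions, X density in input replicate 2 was 1.03 times that of the autosomes. This lay within the range of its single autosomes, 0.924 to 1.06. In every other library X lay below the lowest autosome. H3K27ac, at 1.11 outside peaks, was in the test at first and was taken out after that was seen. The reason was that acetylation is a poor measure of DNA copies on a silenced X. A mixture of sexes could also remain, and age differs between the same libraries.

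The 274090 peaks of Bcl11b formaldehyde replicate 2 were many more than in the other Bcl11b libraries. The gap was smaller at 8-fold, with 53329 peaks in replicate 2, 29890 with EGS plus formaldehyde and 11355 in replicate 1. Against input replicate 1, Bcl11b replicate 2 still had 172923, over 1.5 times the 33066 of the EGS plus formaldehyde library against the same input. The input was therefore not the whole cause. Thinned to the number of distinct positions of replicate 1, Bcl11b replicate 2 had 17218, within 1.5 times both other Bcl11b libraries. That number of positions is thus a candidate explanation, although tags per position still differed. The thinning cannot decide it, since weak peaks are lost at that depth in any library. The 274090 peaks had a median fold of 6.26. In simulation, 4.0% of peaks planted at 10-fold were recovered at that depth. The H3K27ac libraries, with 20935144 and 20194520 positions, had 55133 and 148286 peaks, so like numbers of positions can give unlike peak numbers. No biological explanation was tested.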

How the results depend on the processing

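Chosen after seeing the data were the exchanged inputs, the estimator, the crossed pairing, the fit of both fixations, left-out libraries for peak counts and the fixation share, no input and 50% overlap for the shares, and, for the share with H3K27ac, also 8-fold, all tags and thinning. Bcl11b windows above input numbered 437 with DESeq2, 1 thinned to the smallest library and 7368 with the EGS plus formaldehyde input; the others gave 0, which the 2-fold minimum could only repeat. H3K27ac windows above input numbered 9894 with the replicate block, 6304 by total tags, 12380 with no count filter, 64637 with at least 100 tags, 41841 with only the H3K27ac and input libraries, 5472 with all tags, 36440 thinned, 44120 in windows of 500 bp, 58496 with DESeq2, 0 with the version 4 estimator and 130765 with the EGS plus formaldehyde input. DESeq2 gave no adjusted p for 1215749 of 1279736 windows in the Bcl11b contrast and for 1066882 in that of H3K27ac. The block gave 0 Bcl11b windows. Crossing the input numbers in the block gave 88920 H3K27ac and 0 Bcl11b windows. Without 1 library the count was 0 to 33558; where 1 sample remained, it was assumed to vary like the other groups. The cause of these shifts was not tested.

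Bcl11b peaks of both formaldehyde libraries numbered 7276 at 8-fold, 4023 with input replicate 1 for every library, 30160 with all tags (22.4% of replicate 1) and 7497 thinned, and 4023 to 274090 without 1 library. H3K27ac peaks of both numbered 18446 at 8-fold, 24860 with no input and 19896 thinned, and 39003 to 148286 without 1 library. The share of Bcl11b sites with H3K27ac was 48.9% with 50% overlap, 20.8% at 8-fold, 63.5% with no input, 62.6%, 69.2% and 63.0% with the EGS plus formaldehyde input, input replicate 1 and input replicate 2 throughout, 33.7% with all tags, 63.2% thinned, and 8.46% to 88.5% without 1 library. The share found with EGS plus formaldehyde was 91.7% at 8-fold, 73.0% with no input, 68.0%, 81.5% and 68.1% with those inputs, 48.7% with all tags, 85.9% thinned, and 11.2% to 89.0% without 1 library. Alternatives of the overlap of windows gave no value with 0 Bcl11b windows, and those for promoters, gene lists and motifs were not run. Bcl11b replicate 1 had the fewest distinct positions of the libraries, and among the simulated depths the fewest planted peaks were recovered at its depth.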

Other observations

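All values and tests in this part were chosen after the data were seen.

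Bcl11b sites were densest on chromosome 11, at 8.22 per Mb, and sparsest on X, at 2.13 per Mb. H3K27ac peaks followed the same extremes, with 25.9 per Mb on chromosome 11 and 4.30 on X. Peak numbers were not corrected for coverage. Input density on X was 0.699 times that of the autosomes in replicate 1 and 1.03 times in replicate 2. Fewer peaks on X thus need not mean less binding or acetylation there. The 100 kb bin with the most Bcl11b sites was on chromosome 13 from 23600001 to 23700000. It held 14 sites, all with H3K27ac in both replicates and all found with EGS plus formaldehyde. Of the longest 5% of acetylated regions, 46.1% held a Bcl11b site, against 23.2% of the others, but per 100 kb the longest had 6.10 sites and the others 13.7.

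In the 48323 EGS plus formaldehyde peaks, which were chosen without the formaldehyde libraries, the edgeR quasi-likelihood test called 0 regions with Bcl11b above input (4866 at an unadjusted p under 0.05), and 21410 with H3K27ac above. The H3K27ac count was 6419 with libraries scaled by total tags, 8429 without H3K27ac replicate 1 and 0 without H3K27ac replicate 2, input replicate 1 or input replicate 2. Every Bcl11b library was above every input in 40.6% of the regions, and every H3K27ac library was in 69.8%. Scaled by total tags, these shares were 34.2% and 58.6%. Interchangeable libraries would give 16.7%, but input replicate 1 was itself enriched and the replicate numbers pair the libraries. With the EGS plus formaldehyde input in place of input replicate 1, 14070 regions had Bcl11b above input. The regions had been selected against that input, however.

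Several X windows had H3K27ac in replicate 2 and almost none in replicate 1. The window from 73004001 to 73005000 had 23.6 normalised tags against 0.289, and the window from 100677001 to 100678000 had 22.3 against 0.289. Bcl11b and input rose there too: in the first window Bcl11b was 4.37 in replicate 2 against 0.826 in replicate 1 and input 1.27 against 0.486, and in the second Bcl11b was 2.23 against 0.551 and input 0.970 against 0.292. These windows were picked for their difference and were not tested. The genes there were not looked up for this build, so no explanation is drawn from them here.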
